A study of Mus musculus with 20 samples.

How the data were processed

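RNA was measured in the abdominal and the thoracic aorta of 10 female mice that lacked the LDL receptor (Ldlr) on a C57BL/6J background. By the labels, 5 mice had 2 X chromosomes (XX) and 5 had 1 (XO). The mice were 14 to 18 weeks old and had eaten a high-fat Western diet for 1 week. Each mouse gave 1 library per region, so that 20 libraries fell into 4 groups of 5. Per the labels' protocols, the diaphragm divided the segments, with the aortic root at the upper end of the thoracic one and the iliac bifurcation at the lower end of the abdominal one.

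Polyadenylated RNA was sequenced from 1 end with reads of 100 bp, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, STAR 2.6.1 with the mm10 build of the mouse genome, and Partek Flow 8.0. Per the series' design text, a library held 37.4 ± 2.2 M reads, of which 30.9 ± 1.9 M were kept after alignment (the text does not say whether the error is an SD or an SE). The authors then scaled the counts by TMM (trimmed means of log ratios) in WebMeV. The deposited table holds 19294 genes, where the design text speaks of 19296 before its filter. Its values are on a log2 scale, log2(TMM-scaled abundance + 1), as judged from the values themselves. Back-transformed, the values of a library summed to between 872187 and 1083580. Within each library they were whole multiples of 1 step (100% of the low values, within 0.01 of a whole number), but the multiples summed to between 408 and 548 M per library, far more than the reads. A step was therefore not a read, no counts could be recovered, and no count model was used. The reads behind a single gene's value are unknown.

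Genes with a deposited log2 value of at least 1.5 in at least 2 libraries were kept, which left 14201 genes. The plan had assumed linear values and a step to the log2 scale, which the table already had, so the minimum of 1.5 was applied on the log2 scale. The authors' filter also required protein-coding genes and left 13270. Differences are on the log2(value + 1) scale and understate the change of genes near 0. Coordinates are those of the deposited table on mm10. The protocols do not state whether counting used strand, so overlapping and antisense genes cannot be told apart.

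Group means of all 20 libraries were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend of the variance. Benjamini-Hochberg adjustment over the 14201 genes was used, with a threshold of 0.05, and all tests were two-sided. The 5 comparisons were XO against XX in each region, abdominal against thoracic in each genotype, and the genotype by region interaction. Of 30 gene lists, 28 were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The Y-linked and pseudoautosomal lists had too few tested members and are given as values. The lists, the design and most of the other settings tried were fixed before the data were examined. Lists of neuronal and of liver genes were added after the first results. Named genes followed a rule: for each pairwise comparison the 8 highest and 8 lowest changes among called genes above the 25th percentile of mean level whose groups did not overlap. Where no gene was called, the 5 smallest p-values in each direction were named as values. Up to 4 members of each list were also eligible. Genes numbered as predictions were counted but not named. Msl3 and Hccs were named after their values were seen.

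Both regions came from the same mice, so the mouse number pairs the libraries. The deviations of the 2 libraries of a mouse from their group means correlated across genes with a median r of 0.19 (-0.10 to 0.40), against -0.083 for libraries of different mice. The fit reported has no block, as the design text names none, and fits with the mouse as a block are alternatives. Other alternatives were the filter, the pseudocount, the scaling, the variance model, library weights, RNA integrity as a covariate, the Storey q-value and leaving out each library. After the data were seen, fits without mice 165 and 173, and without the abdominal libraries of mice 163, 164 and 173, were added, as was a test of RNA integrity with the libraries of a mouse as pairs.

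The model was tested on simulated data with 14201 genes. Of the genes changed by 1 on the log2 scale, 90% were recovered for genotype in abdominal aorta and 80% in thoracic aorta, and 72% and 74% for region in mice labelled XX and XO. At a change of 0.5, 46%, 32%, 40% and 48% were recovered. False calls among the 14001 unchanged genes numbered 52, 22, 29 and 16 in these 4 comparisons, or 23.7%, 12.6%, 15.9% and 9.20% of all calls, above the nominal 5%. Only 50 genes were changed at each simulated size, and genes were drawn independently. These shares therefore do not carry over to the real region comparisons, which called far more genes. Calls near the threshold may still be less certain than the adjusted p states.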

Results

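The series asked how the loss of 1 X chromosome relates to gene expression along the aorta of female mice. Expression was profiled in abdominal and thoracic aorta of mice labelled XX or XO, with 5 mice and 5 libraries per group. Each library showed between 16727 and 18534 genes above 0. The first principal component held 59.1% of the variance and the second 16.2%. The abdominal libraries of mice 163 and 164 lay between the regions on the first, at 4.90 and -1.30, where the other abdominal libraries ranged from -88.0 to -51.0 and the thoracic ones from 34.9 to 56.9. Both correlated better with the other region (mean r 0.955 and 0.952) than with their own group (0.906 and 0.947). RNA integrity numbers averaged 8.96 ± 0.270 (SD, n = 5) and 9.04 ± 0.134 for abdominal and thoracic libraries labelled XX, and 8.80 ± 0.158 and 9.06 ± 0.0548 for those labelled XO. The largest difference, -0.26 between the regions of mice labelled XO, had an exact permutation p of 0.0238 with the libraries unpaired (0.0952 after adjustment over 4 comparisons). With the pairing by mouse, 4 of 5 mice were lower and 1 equal, and exact sign flips gave p = 0.125, where 5 pairs can give no less than 0.0625.

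Xist, the RNA that coats and silences an X chromosome in cells with more than 1, was measured first as a check of the labels. It ran against the label in both libraries of 1 mouse of each genotype. Mouse 165, labelled XO, had log2 values of 9.38 in abdominal and 9.05 in thoracic aorta, where the other mice labelled XO lay between 0.32 and 1.88. Mouse 173, labelled XX, had 0.62 and 0.84, where the other mice labelled XX lay between 9.05 and 9.69. Eif2s3x, a translation factor gene that escapes silencing, was 6.98 and 7.25 in mouse 165 against 6.12 to 6.59 in the other mice labelled XO, and 6.23 and 6.41 in mouse 173 against 6.89 to 7.31 in the others labelled XX. The histone demethylase gene Kdm5c showed the same crossing, at 5.95 and 6.01 in mouse 165 and 5.42 and 5.34 in mouse 173. Of 9 listed escape genes other than Xist, 4 did not leave the range of the own label in either library of mouse 165, Ddx3x and Jpx among them, and 1, Ddx3x, did not in the thoracic library of mouse 173. Y-linked genes were near 0 throughout, with Ddx3y at 0.28 or lower in each library. The pseudoautosomal gene Erdr1 ranged from 2.39 to 3.32 in mice labelled XO other than 165 and from 2.25 to 3.13 in those labelled XX other than 173. All mice were kept under their labels, so every direction between genotypes below refers to libraries labelled XO and XX.

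**Figure D1:**
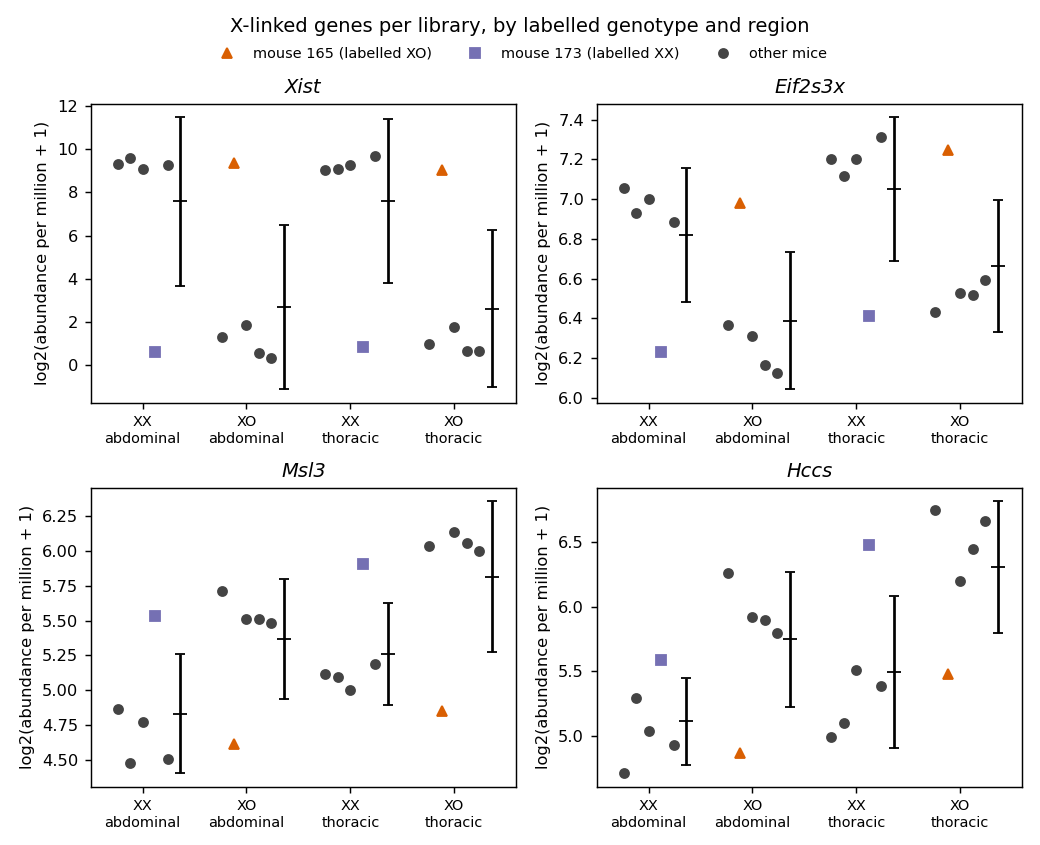
Log2 values of Xist, Eif2s3x, Msl3 and Hccs in each of the 20 libraries, by labelled genotype and region, with the mean and SD of each group of 5 as bars. The Xist values of mouse 165 (9.38 and 9.05) and mouse 173 (0.62 and 0.84) lie among those of the other label.

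In abdominal aorta, Xist averaged 2.69 ± 3.79 (SD, n = 5) in libraries labelled XO and 7.58 ± 3.89 in those labelled XX, a difference of -4.89 ± 2.23 (SE) that did not pass the test. Eif2s3x differed by -0.43 ± 0.21 and Kdm6a, another histone demethylase gene, by -0.39 ± 0.19, neither past the test. Limma called 0 of 14201 genes between the genotypes, with 512 at an unadjusted p under 0.05 where chance gives 710. The smallest unadjusted p-values belonged to Akr1c14 (-1.43 ± 0.31), Perp (-0.63 ± 0.16), Snord118 (-2.06 ± 0.54), Txndc15 (-0.22 ± 0.06) and Tsku (-0.47 ± 0.13) on the lower side. On the higher side they were Mapk1ip1 (0.24 ± 0.06), Mapk12 (0.20 ± 0.06), Papolb (0.71 ± 0.21), Mir6236 (2.98 ± 0.91) and Tacstd2 (1.01 ± 0.32). With the preset correlation, camera called 9 of 28 lists, 4 up and 5 down, among them X escape genes (median -0.23, adjusted p = 0.00147) and macrophage genes (median -0.13, adjusted p = 0.00155). Both had an adjusted p = 0.858 with an estimated correlation. With the mouse as a block the calls of the inflammatory and white adipocyte lists were lost (adjusted p = 0.0548 for both). No list member passed over all genes or adjusted over the list alone.

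In thoracic aorta, Xist differed by -4.96 ± 2.23, Kdm5c by -0.43 ± 0.17 and Eif2s3x by -0.39 ± 0.21 between libraries labelled XO and XX, none past the test. Limma called 0 genes, with 258 at an unadjusted p under 0.05. The smallest unadjusted p-values on the lower side were those of Pou5f2 (-0.70 ± 0.16), Snora21 (-3.04 ± 0.70), Akr1c18 (-0.61 ± 0.18), Magef1 (-0.42 ± 0.12) and Tas1r3 (-0.43 ± 0.13). Those on the higher side were Slitrk6 (0.46 ± 0.13), Cxcl14 (0.52 ± 0.15), Dnaja4 (0.28 ± 0.09), Cyp51 (0.31 ± 0.10) and Myl7 (2.59 ± 0.84), a cardiac myosin light chain. Camera called 11 of 28 lists with the preset correlation, 7 up and 4 down. Cardiac muscle genes had the largest median, 1.74 (adjusted p = 1.84e-13), and X escape genes a median of -0.39 (adjusted p = 1.62e-06), each with an adjusted p = 0.284 with an estimated correlation. Again 0 members of any list passed, over all genes or adjusted over the list alone.

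Genes on the X chromosome outside the escape list did not move as a set. The 456 tested ones had a median log2 difference between mice labelled XO and XX of 0.0193 in abdominal aorta (camera p = 0.322, or 0.636 with an estimated correlation) and 0.00774 in thoracic aorta (camera p = 0.505, or 0.749). Autosomal genes had medians of 0.00829 and 0.000959. Across genes, the genotype differences of the 2 regions had a Pearson r of -0.0763 (permutation of mice p = 0.891 over 100 draws, median r of the draws 0.154). Genes are not independent replicates.

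Without mice 165 and 173, chosen after their Xist values were seen, 4 mice per label remained and genes of the X chromosome were called in both regions. Limma called 6 genes in abdominal aorta (2 higher and 4 lower in mice labelled XO) and 7 in thoracic aorta (2 and 5). Xist (X, 103460373 to 103483233) was lower by -8.30 ± 0.31 (SE) and -8.25 ± 0.31 in abdominal and thoracic aorta. The lower escape genes were Eif2s3x (X, 94188709 to 94212651; -0.73 ± 0.07 and -0.69 ± 0.07), Kdm6a (-0.68 ± 0.09 and -0.67 ± 0.09) and Kdm5c (-0.50 ± 0.08 and -0.70 ± 0.08). Pbdc1 was -0.38 ± 0.08 in abdominal aorta (adjusted p = 0.512) and was called in thoracic aorta at -0.52 ± 0.08 (adjusted p = 0.0215). These calls follow in part from how the mice were left out. Msl3 (X, 168653099 to 168673902), which encodes a chromatin protein of the MSL complex, was higher in mice labelled XO by 0.90 ± 0.09 (adjusted p = 0.000258) and 0.96 ± 0.09 (adjusted p = 0.000175). Hccs (X, 169311531 to 169320372), which encodes the enzyme that attaches haem to cytochrome c, was higher by 0.97 ± 0.16 (adjusted p = 0.0471) and 1.27 ± 0.16 (adjusted p = 0.00282). With all mice the differences were 0.54 and 0.56 for Msl3 and 0.63 and 0.81 for Hccs, not past the test. The X escape list had medians of -0.45 and -0.52 (adjusted p = 7.53e-05 and 3.21e-05 with an estimated correlation). Cardiac muscle genes had a median of 2.66 in thoracic aorta (adjusted p = 0.0212 with an estimated correlation), with 0 of 14 members higher over all genes and 10 adjusted over the list alone. With all mice, the mean level of this list ranged from 1.97 to 6.89 over the thoracic libraries labelled XO. It ranged from 1.77 to 4.31 over those labelled XX. How much heart tissue each library held was not measured, so this difference cannot be read as one of the aortic wall. In each region another grouping of these 8 mice gave more genes, at most 974 and 21.

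**Figure D2:**
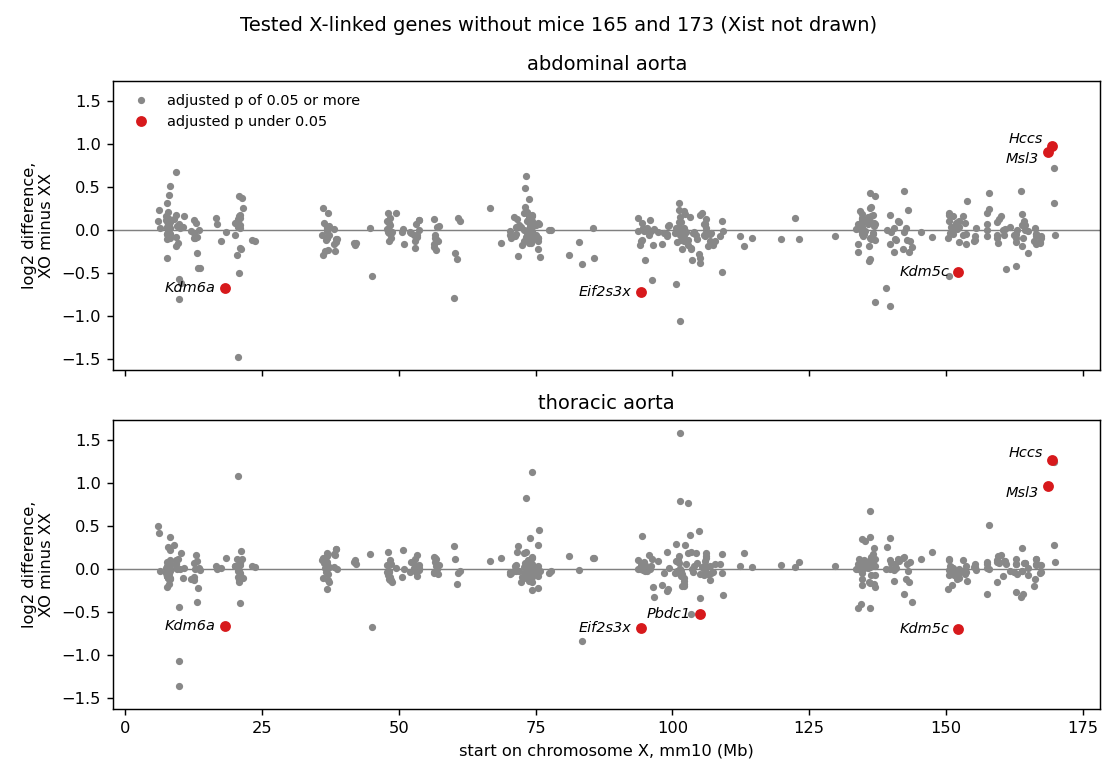
Log2 difference between libraries labelled XO and XX of each tested X-linked gene other than Xist against its start on mm10, without mice 165 and 173 (4 mice per label). Msl3 and Hccs lie near the distal end above 0, at 0.90 and 0.97 in abdominal aorta and 0.96 and 1.27 in thoracic aorta, and the called escape genes lie below 0.

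The regions differed far more than the genotypes. In mice labelled XX, 6307 genes passed the test (3065 higher and 3242 lower in abdominal aorta), 1716 of them by at least 1 on the log2 scale (1397 higher and 319 lower). In mice labelled XO, 6498 passed (3027 higher and 3471 lower), 1588 by at least 1 (1211 and 377). Of these, 5121 were called in the same direction in both genotypes, 2470 higher where independent lists would share 653 and 2651 lower where they would share 792, and 0 in opposite directions. The share of calls that were higher was 48.6% and 46.6%, and 30.2% and 35.9% under quantile normalization, which moved the median difference of all genes in mice labelled XX from -0.04 to -0.15. Without mice 165 and 173, 4852 and 5727 genes passed, and without the abdominal libraries of mice 163, 164 and 173, 6045 and 7228.

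Genes known from sympathetic neurons were among the most raised of the named genes in abdominal aorta. Dbh (2, 27165507 to 27183204), which encodes the enzyme that makes noradrenaline, averaged 8.68 ± 1.34 (SD, n = 5) in abdominal and 0.48 ± 0.67 in thoracic libraries labelled XX, a rise of 8.20 ± 0.86 (SE, adjusted p = 2.78e-06). In mice labelled XO it rose by 7.96 ± 0.86 (adjusted p = 2.44e-06). Th, the rate-limiting enzyme of catecholamine synthesis, rose by 8.02 ± 0.81 and 7.82 ± 0.81 in mice labelled XX and XO. Prph, Nefl and Nefm, which encode neuronal intermediate filaments, rose by 7.73, 7.69 and 7.24 in mice labelled XX. Npy, a transmitter of sympathetic nerves, rose by 7.62, the vesicle genes Scg2 and Syt4 by 7.23 and 7.17, and Slc6a2, the noradrenaline transporter, by 7.07 in mice labelled XO. The Schwann cell genes Plp1 and Sox10 rose by 3.06 ± 0.31 and 3.07 ± 0.32 in mice labelled XX. Of the 16 Schwann and neural genes tested, 13 rose and 1 fell in mice labelled XX, and 13 rose and 0 fell in those labelled XO, with the same counts adjusted over the list alone. Camera gave adjusted p = 5.69e-08 and 1.2e-08, and adjusted p = 0.383 and 0.353 with an estimated correlation.

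Contractile smooth muscle genes were lower in abdominal aorta. Acta2 (19, 34240336 to 34255373), smooth muscle actin, averaged 11.08 ± 0.54 (SD, n = 5) in abdominal and 12.68 ± 0.42 in thoracic libraries labelled XX, a difference of -1.60 ± 0.25 (SE, adjusted p = 0.000114), and fell by 1.67 ± 0.25 in those labelled XO. Cnn1, calponin, fell by 1.57 and 1.73, and the integrin gene Itga8 by 1.99 and 2.10. Of 17 tested members 16 fell and 0 rose in each genotype, also adjusted over the list alone (camera adjusted p = 5.9e-07 and 5.67e-07, or adjusted p = 0.646 and 0.586 with an estimated correlation). Elastic fibre and collagen genes followed, with 15 of 24 lower in each genotype and 1 and 2 higher (15 lower and 2 higher adjusted over the list alone in each). Camera gave adjusted p = 0.00246 and 0.00618, and adjusted p = 0.666 and 0.702 with an estimated correlation. Postn, a matricellular protein, fell by 1.65 and 1.76, and the microfibril gene Mfap5 by 1.41 and 1.45. Sost, an inhibitor of Wnt signalling, fell by 2.97 and 2.91, from 10.32 ± 0.51 (SD) in thoracic libraries labelled XX. Among the other lower genes were Olfr224 (-3.34 and -3.32), Fam84a (-2.61 and -2.77), the channel gene Kcnj15 (-2.35 and -2.47), the transcription factor gene Foxf1 (-2.35 and -2.62), Mia (-2.28 and -2.29) and the sarcoglycan gene Sgcg (-2.26 and -2.49).

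Genes of TGF-beta signalling and of heritable aortopathy were mostly lower in abdominal aorta. Of 20 TGF-beta genes 15 fell and 2 rose in mice labelled XX, and 11 fell and 1 rose in those labelled XO (15 and 12 lower adjusted over the list alone). The ligand gene Tgfb2 fell by 1.10 ± 0.19 and 1.25 ± 0.19, and Ltbp2, a latent TGF-beta binding protein, by 1.34 ± 0.20 and 1.20 ± 0.20. Camera gave adjusted p = 0.000705 and 0.00202, and adjusted p = 0.646 and 0.586 with an estimated correlation. Of 20 aortopathy genes 16 and 14 fell and 2 rose in each genotype (16 and 15 lower adjusted over the list alone). Many of these are also members of the contractile, matrix or TGF-beta lists, Acta2, Fbn1 and Tgfb2 among them. The aortopathy counts are therefore not a separate result from those lists. The receptor gene Notch1 was a riser, by 0.61 ± 0.09 and 0.70 ± 0.09. The list had adjusted p = 0.000619 and 0.0013, and adjusted p = 0.646 and 0.586 with an estimated correlation. In the renin-angiotensin list 5 of 11 rose and 2 fell in mice labelled XX, and 4 and 2 in those labelled XO, also adjusted over the list alone (camera adjusted p = 0.4 and 0.328). Agtr1a, the main angiotensin II receptor, rose by 2.50 ± 0.39 and 2.44 ± 0.39, while Ace, the angiotensin converting enzyme, fell by 1.41 ± 0.23 and 1.18 ± 0.23.

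Hox genes, which set position along the body axis, differed between regions, in directions that went with both paralog number and cluster. A difference between the paralog lists or the clusters was not itself tested. Of 17 tested genes of paralogs 6 to 11, 11 were higher in abdominal aorta in each genotype and 2 and 1 lower (12 and 11 higher adjusted over the list alone). Hoxc10 (15, 102966796 to 102971897) averaged 5.20 ± 0.49 (SD, n = 5) in abdominal and 0.19 ± 0.27 in thoracic libraries labelled XX, a rise of 5.01 ± 0.23 (SE, adjusted p = 1.48e-10), and rose by 4.44 ± 0.23 in mice labelled XO (adjusted p = 6.17e-10). Hoxc9 rose by 3.19 and 2.84 and Hoxa10 by 3.31 and 2.83. Hoxa11 was listed at 0 in all 10 thoracic libraries and averaged 2.74 and 2.61 in abdominal ones. The list had camera adjusted p = 1.16e-06 and 1.08e-05, and adjusted p = 0.383 and 0.538 with an estimated correlation. Of 12 genes of paralogs 1 to 5, 9 were lower in each genotype and 3 and 2 higher, also adjusted over the list alone (camera adjusted p = 0.00558 and 0.00618, and adjusted p = 0.646 and 0.586 with an estimated correlation). Hoxb2 fell by 1.51 and 1.38 and Hoxa4 by 1.48 and 1.30, whereas Hoxd4 rose by 1.11 and 1.08. By cluster, a grouping made after the values were seen, the tested HoxC and HoxD genes lay above 0 and most HoxB genes below 0 at low and high paralog numbers alike, while HoxA genes parted by paralog number. In each genotype 5 of 5 HoxA genes of paralogs 1 to 5 fell, and of 5 of paralogs 6 to 11, 3 rose, 4 lay above 0 and 1 below (5 above in mice labelled XX under fresh TMM scaling). Of 2 HoxC genes of paralogs 1 to 5, 2 rose in mice labelled XX and 1 in those labelled XO, and 5 of 5 of paralogs 6 to 11 rose in each. HoxB genes of paralogs 6 to 11 gave 0 higher in each genotype and 2 and 1 lower of 4. The numbers of HoxB, HoxC and HoxD genes above and below 0 stayed as they were under fresh TMM scaling and quantile normalization.

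**Figure D3:**
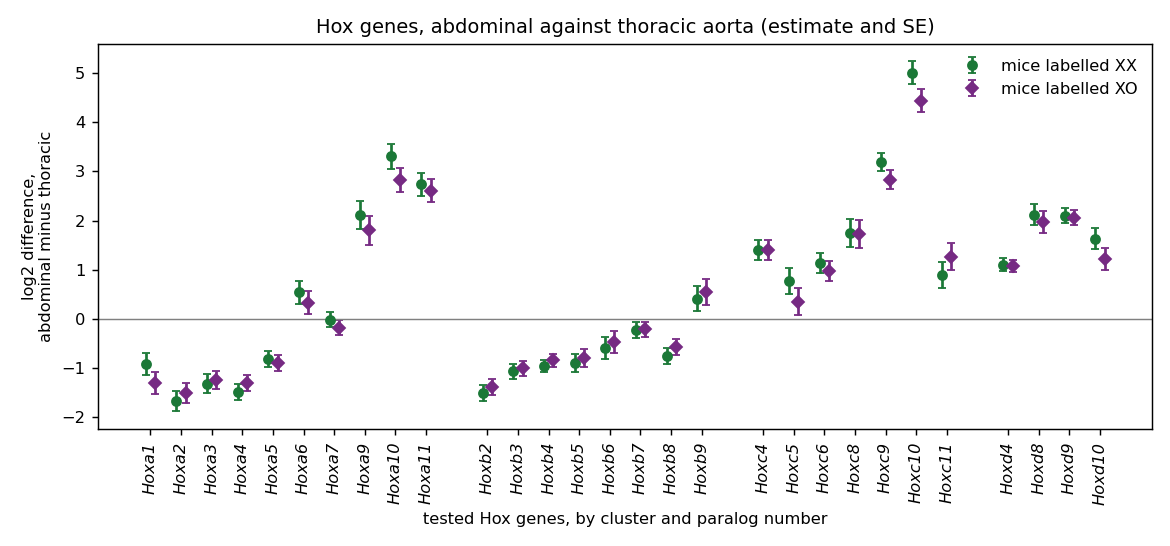
Log2 difference between abdominal and thoracic aorta with its SE for each tested Hox gene, ordered by cluster and paralog number, in mice labelled XX (circles) and XO (diamonds), 5 libraries per group. Hoxc10 lies highest at 5.01 and 4.44, and Hoxa4 and Hoxb2 lie below 0.

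Lipid synthesis and interferon genes were higher and mitochondrial genes lower in abdominal aorta. Of 20 cholesterol and fatty acid synthesis genes 15 rose in mice labelled XX and 13 in those labelled XO (16 and 13 adjusted over the list alone) and 0 fell. Mvd and Sqle, enzymes of cholesterol synthesis, rose by 1.62 ± 0.20 and 1.53 ± 0.22 in mice labelled XX. The list had camera adjusted p = 1.15e-06 and 1.22e-05, and adjusted p = 0.46 and 0.586 with an estimated correlation. Of 18 interferon response genes 9 and 13 rose, also adjusted over the list alone (adjusted p = 0.00181 and 0.000111, and adjusted p = 0.646 and 0.586 with an estimated correlation), with Ifit1 up by 1.59 ± 0.37 and 1.76 ± 0.37. Of 20 oxidative phosphorylation genes 19 fell in each genotype (20 adjusted over the list alone). This count was 9 and 7 without mice 165 and 173, 7 and 20 without the abdominal libraries of mice 163, 164 and 173, and 12 and 11 under quantile normalization, with medians below 0 in each. Cox6c, a subunit of cytochrome c oxidase, fell by 0.83 ± 0.16 and 0.82 ± 0.16. The list had adjusted p = 2.05e-05 and 5.71e-05, and adjusted p = 0.646 and 0.586 with an estimated correlation. Brown adipocyte genes fell in 9 and 11 of 15 cases, also adjusted over the list alone, among them Prdm16, a regulator of brown fat identity (-0.95 and -0.83). Camera gave adjusted p = 0.003 and 0.00249, and adjusted p = 0.646 and 0.586 with an estimated correlation. White adipocyte genes rose in 3 of 16 cases in each genotype, also adjusted over the list alone (adjusted p = 0.177 and 0.136), with Retn, resistin, up by 1.80 and 2.06. The mean level of that list was 9.18 and 9.31 in abdominal libraries labelled XX and XO, and 8.77 and 8.82 in thoracic ones. That of the brown adipocyte list was 6.12 and 6.20 in abdominal and 6.83 and 6.99 in thoracic libraries. How far fat tissue in the libraries bears on the lipid synthesis and mitochondrial genes was not tested.

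Some immune cell genes were higher in abdominal aorta. Of 17 macrophage genes 5 and 8 rose and 1 fell in each genotype, also adjusted over the list alone. Cd74 rose by 0.84 ± 0.17 and 1.18 ± 0.17, while the engulfment receptor gene Mertk fell by 0.66 and 0.73. Camera gave adjusted p = 0.0194 and 0.0204, and adjusted p = 0.646 and 0.59 with an estimated correlation. With the mouse as a block the macrophage call was lost (adjusted p = 0.0575 and 0.0628). Of 13 lymphocyte genes 2 and 4 rose (0 and 3 adjusted over the list alone). That list was called in mice labelled XO (adjusted p = 0.0339), not with the block (adjusted p = 0.0997) nor with an estimated correlation (adjusted p = 0.687), and had adjusted p = 0.0936 in those labelled XX. The chemokine receptor gene Ccr2 rose by 0.95 and 0.98, in an inflammatory list where 4 and 5 of 19 rose and 0 and 1 fell, also adjusted over the list alone (adjusted p = 0.0936 and 0.232). Among genes known from lymphatic endothelium, Mmrn1 rose by 1.88 ± 0.15 and 1.74 ± 0.15 and Ccl21a by 2.45 and 2.39. In the lymphatic and mesothelial list of 13, 4 rose in each genotype and 0 and 3 fell (0 and 4 lower adjusted over the list alone). It had adjusted p = 0.061 in mice labelled XX, or 0.00709 with the mouse as a block, and 0.232 in those labelled XO. Endothelial genes rose in 5 and 4 of 16 cases and fell in 1 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.154 and 0.217). Fibroblast genes rose in 2 and fell in 1 of 13 cases, also adjusted over the list alone (adjusted p = 0.4 and 0.255), with Clec3b up by 0.78 and 0.90 and Pi16 down, at -0.96 and -0.85.

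Genes of neighbouring tissues varied between libraries. Of 14 heart muscle genes, 3 were lower in abdominal aorta in mice labelled XX and 11 in those labelled XO, also adjusted over the list alone. Myh6, a cardiac myosin heavy chain, fell by 3.72 ± 1.00 and 6.32 ± 1.00, and Myl7 by 3.67 ± 0.84 and 6.40 ± 0.84. Camera gave adjusted p = 0.0399 and 0.000541, and adjusted p = 0.666 and 0.586 with an estimated correlation, and with the mouse as a block the call in mice labelled XX was lost (adjusted p = 0.0579). The mean level of the list ranged from 1.97 to 6.89 over the thoracic libraries labelled XO. Skeletal muscle genes gave 1 and 2 lower members of 15 (1 in each adjusted over the list alone; adjusted p = 0.789 and 0.518), among them Casq1 (-2.16 and -2.53). Their mean level reached 5.78 in the abdominal library of mouse 163, 5.17 in that of mouse 164, 3.38 in that of mouse 175 and 4.37 in the thoracic library of mouse 173. Adrenal and kidney genes gave 0 of 5 (adjusted p = 0.209 and 0.232) and blood cell genes 0 of 13 (adjusted p = 0.789 and 0.684), over all genes and adjusted over the list alone. The mean level of the adrenal and kidney list varied, from 1.24 to 6.35 over the abdominal libraries labelled XX. Over the abdominal libraries labelled XO it ranged from 0.96 to 5.29. The thoracic ranges were 0.73 to 3.01 and 0.80 to 0.92 in libraries labelled XX and XO. The remaining lists were not called. Matrix proteases and their inhibitors gave 3 and 4 higher and 5 and 7 lower of 20, also adjusted over the list alone (adjusted p = 0.789 and 0.684). Cell cycle genes gave 3 and 1 higher and 1 lower of 12, or 1 and 0 higher and 0 and 1 lower adjusted over the list alone (adjusted p = 0.0936 and 0.518). Stress genes gave 2 and 3 lower of 18, or 1 and 2 adjusted over the list alone (adjusted p = 0.105 and 0.0598). Clock genes, Hlf and Clock among them, gave 6 and 5 lower of 16, or 5 in each adjusted over the list alone (adjusted p = 0.0936 and 0.0766). X escape genes gave 0 and 1 lower of 9, or 0 adjusted over the list alone (adjusted p = 0.384 and 0.584).

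**Figure D4:**
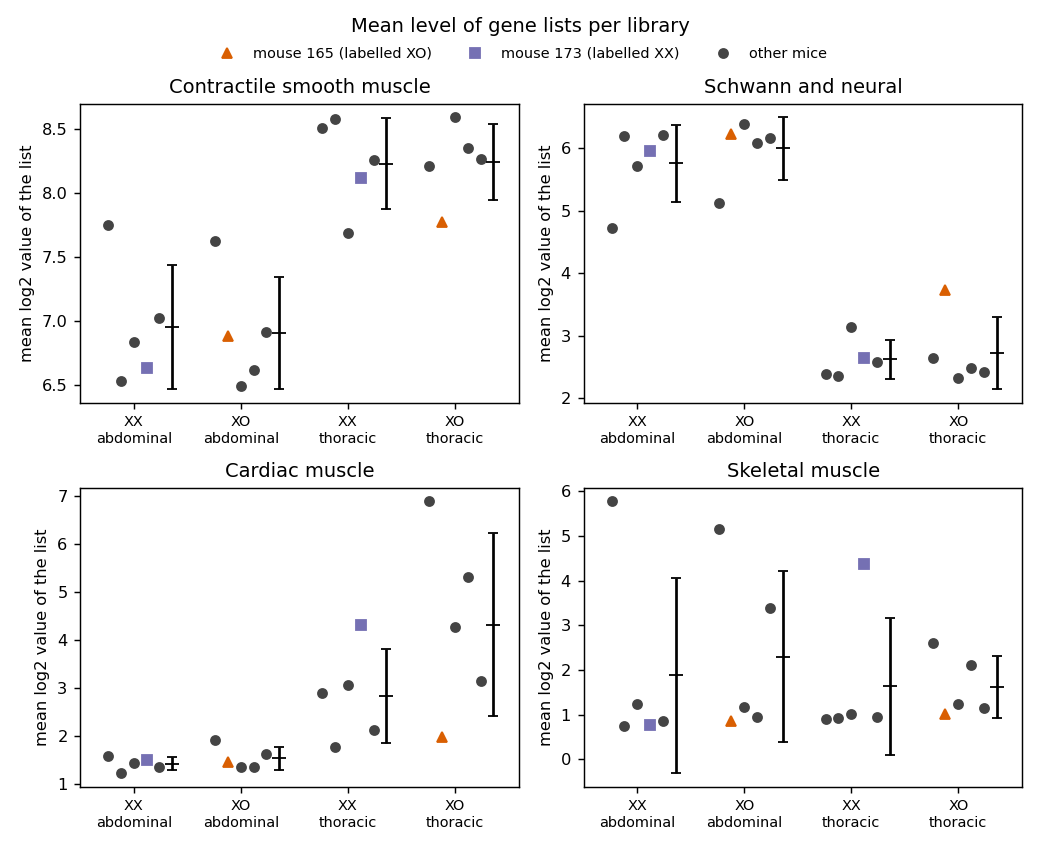
Mean log2 value of 4 gene lists in each of the 20 libraries, by labelled genotype and region, with the mean and SD of each group of 5 as bars. Contractile genes lie lower and neural genes higher in abdominal libraries, and skeletal muscle genes reach 5.78 and 5.17 in the abdominal libraries of mice 163 and 164.

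The difference between regions was not called as different between genotypes for any gene. Limma called 0 genes for the interaction, with 176 at an unadjusted p under 0.05. The smallest unadjusted p-values were those of Pou5f2 (0.81 ± 0.22), Sfn (0.66 ± 0.20), Tacstd2 (1.45 ± 0.45), Ccar2 (0.25 ± 0.08) and Moap1 (1.18 ± 0.38) on the higher side. On the lower side they were Snord118 (-2.65 ± 0.76), Sar1b (-0.44 ± 0.13), Rnf13 (-0.35 ± 0.10), Txndc15 (-0.26 ± 0.08) and Lamp2 (-0.42 ± 0.14). Of 28 lists, camera called cardiac muscle with a median of -1.55 (adjusted p = 8.55e-06, and adjusted p = 0.994 with an estimated correlation). No member passed over all genes or adjusted over the list alone.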

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

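Of the tests below, those of wrong labels, of mixed RNA, of the smooth muscle share, of neighbouring tissues and of a general rise of the X, and the splits for the genotype and interaction counts, were chosen after the result was seen, and the others before.

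In 97 of 480 groups of 5 libraries checked, 1 library stood apart from the other 4, where chance gives about 1 in 20, or 24. Values in brackets are the gap to the nearest library as a share of the group's range. Genes of 1 list move together, so the 97 are not independent. Of these, 26 came from the abdominal library of mouse 164, 22 from the thoracic library of mouse 165 and 12 from the abdominal library of mouse 163. The cardiac muscle list differed between genotypes in its region difference (-1.55, adjusted p = 8.55e-06 at the preset correlation and 0.994 with an estimated one).

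The abdominal library of mouse 164 (labelled XO) stood above its group for Fam84a (0.795), Sgcg (0.843), Itga8 (0.755), Postn (0.808), Tgfb2 (0.746), Mir6236 (0.754), the elastic fibre and collagen matrix list (0.774) and the TGF-beta signalling list (0.79). Further values above the group were those of the heritable aortopathy list (0.713) and the Hox paralogs 1 to 5 list (0.836). It stood below for Dbh (0.823), Th (0.866), Prph (0.792), Nefl (0.739), Npy (0.817), Nefm (0.739), Scg2 (0.805) and Syt4 (0.753). Further values below the group were those of Slc6a2 (0.747), Agtr1a (0.762), Notch1 (0.752), Phox2b (0.731), Sox10 (0.732), Kif5a (0.757), Ccar2 (0.751) and the Schwann and neural list (0.761).

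The thoracic library of mouse 165 (labelled XO) stood above its group for Xist (0.864), Kdm5c (0.814), Eif2s3x (0.805), Dbh (0.958), Th (0.898), Prph (0.869), Nefl (0.876) and Npy (0.956). Further values above the group were those of Nefm (0.92), Scg2 (0.726), Syt4 (0.933), Slc6a2 (0.900), Enpep (0.844), Hoxd4 (0.729), Phox2b (0.726) and Kif5a (0.882). So were those of Snap25 (0.951), the X escape list (0.871) and the Schwann and neural list (0.777). It stood below for Msl3 (0.896), Kcnj15 (0.722) and Foxf1 (0.891).

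The abdominal library of mouse 163 (labelled XX) stood above its group for Fam84a (0.759), Casq1 (0.765), Hoxa10 (0.732), the elastic fibre and collagen matrix list (0.719), the matrix proteases and inhibitors list (0.728), the TGF-beta signalling list (0.883), the heritable aortopathy list (0.76) and the skeletal muscle list (0.901). It stood below for Dbh (0.739), Th (0.728), Prph (0.744) and Scg2 (0.74).

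The thoracic library of mouse 173 (labelled XX) stood above its group for Msl3 (0.798), the inflammatory cytokines and adhesion list (0.794) and the skeletal muscle list (0.966). It stood below for Xist (0.928), Kdm6a (0.781), Kdm5c (0.758), Eif2s3x (0.779), Pbdc1 (0.72) and the X escape list (0.896).

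The abdominal library of mouse 173 stood above its group for Prox1 (0.711) and Mir6236 (1). It stood below for Xist (0.941), Kdm6a (0.781), Eif2s3x (0.796), Mia (0.713), the X escape list (0.865) and the circadian clock list (0.833).

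The abdominal library of mouse 165 stood above its group for Xist (0.829), Eif2s3x (0.717) and the X escape list (0.782). It stood below for Msl3 (0.789), Enpep (0.725) and Flt4 (0.834).

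The remaining single values came from other libraries. They were Jpx (0.757, mouse 175, abdominal, below), Myl7 (1, mouse 172, abdominal, above), Postn (0.74, mouse 171, thoracic, below), Agtr2 (0.723, mouse 163, thoracic, below), Flt4 (0.754, mouse 164, thoracic, below), Mapk12 (0.826, mouse 180, abdominal, below) and Snord118 (1, mouse 172, thoracic, above). The others were Snord118 (0.744, mouse 180, abdominal, below), Snora21 (1, mouse 172, thoracic, above), Moap1 (0.727, mouse 171, abdominal, above), the adrenal, renal and steroid list (0.953, mouse 163, thoracic, above), the cell cycle list (0.712, mouse 174, abdominal, above), the immediate early and stress list (0.744, mouse 172, abdominal, below) and the immediate early and stress list (0.733, mouse 171, thoracic, below).

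The labels of mice 165 and 173 are in doubt, because Xist, Kdm6a, Kdm5c, Eif2s3x and Pbdc1 ran with the other label in both regions, and of 9 listed escape genes other than Xist, 5 in each library of mouse 165 and 9 and 8 in the abdominal and thoracic libraries of mouse 173 lay outside the range of the other mice of the own label. Those inside were Ddx3x, Jpx, Ftx and 5530601H04Rik in mouse 165 and Ddx3x in the thoracic library of mouse 173, and for these genes the ranges of the labels overlap. On a scale where 0 is the mean of the own label and 1 that of the other, the 8 tested escape genes other than Xist were averaged, without Ftx. Their mean position was 1.03 over the 4 libraries. The test needed 0.75 in each library, which 3 of 4 reached, while the thoracic library of mouse 165 had 0.711. Mid1, 1 of the 8, was higher in mice labelled XO without mice 165 and 173, at 1.39 against 1.11 in thoracic aorta. It was 0.93 in the thoracic library of mouse 165, and positions without Mid1 were not computed. Msl3 lay at 1.05 and 1.26 in mouse 165 and 0.978 and 0.841 in mouse 173, and Hccs at 1.13, 0.816, 0.611 and 0.970. The criterion as written could be read as a mean, which would have passed; the stricter reading was kept after both values were seen, so wrong labels may explain the pattern but cannot be told apart from a true loss or gain of an X in these mice, for want of a genotype measured on DNA. A large share of XO RNA mixed with XX RNA in mouse 165 is argued against by its Xist. It lay 0.279 SD above the mean of the other 4 mice labelled XX in abdominal aorta and -0.793 SD from it in thoracic aorta. A small share would move Xist by less than the spread of those mice, so it cannot be excluded.

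Of 100 splits of the 10 libraries, 1 gave as many genes between regions in each genotype, the real one. The counts were 6307 against at most 4370 in mice labelled XX, and 6498 against at most 4400 in those labelled XO. The 100 held all 16 splits that part the 2 libraries of every mouse, and the rest were drawn from the others. Those others treat the 2 libraries of a mouse as independent, so the share of 100 does not exclude chance. Among the 16 splits that part the 2 libraries of every mouse, the real one was the highest and the others gave at most 2255 and 3603, but 16 splits are too few for a share under 5%. A lower share of smooth muscle alone is argued against for the neural genes, as their list rose more than the endothelial list by 2.97 ± 0.386 (SE, n = 5) and 3.12 ± 0.338. The neural rise was already known when this test was chosen. The test cannot tell whether a lower share underlies the falls of contractile, matrix, TGF-beta and aortopathy genes, which stays open. Without the abdominal libraries of mice 163, 164 and 173, 86.8% of calls in mice labelled XX stayed. This argues against neighbouring tissue in the libraries of mice 163 and 173 as the whole cause in mice labelled XX. Mouse 164 is labelled XO, so that share does not test its library. A list of 20 general neuronal genes, of which 19 passed the filter and all 19 rose, had medians of 3.30 and 3.58 (Kif5a 6.10 and Snap25 4.86 in abdominal libraries labelled XX). Its test was set before its own values were seen, but the list was added after the first results and in part restates the neural genes above. Ganglion or nerve tissue along the abdominal segment is thus a candidate source of the neuronal part. Dissection and a true difference in innervation both stay open, as do the untested regional differences of the wall itself, such as those of Hox genes.

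Msl3 and Hccs lie near the distal end of the X and were higher in mice labelled XO without mice 165 and 173. A general rise of the single X is argued against, as the 452 other tested X genes that start before Msl3, escape genes left out, had medians of -0.0133 and 0.00718. An extra copy of the distal segment could not be decided: beyond Hccs and the listed escape gene Mid1 (0.31 and 0.28), only 2 tested genes lie distal of Msl3, with medians of 0.329 and 0.656, where 0.4 in both regions was needed and under 0.1 would have excluded it. These 2, named after their values were seen, moved apart, with 4933400A11Rik at 0.71 and 1.24 and G530011O06Rik at -0.06 and 0.08. Both lie within the span of Mid1, which was also listed as pseudoautosomal, so G530011O06Rik cannot show where a segment would end. Among genes distal of Msl3 that did not pass the filter, Arhgap6 differed by 0.34 and 0.53 and Gm15246 by 0.21 and 0.19. Amelx differed by 0.05 and -0.02. All of these had low values. Chance is not excluded for the counts of 6 and 7 genes, as 4 and 2 of 35 splits of the 8 mice, the real one included, gave as many. The other splits gave at most 974 and 21.

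For the counts of 0 genes by genotype and for the interaction, 100 of 100 splits of the 10 mice gave as many in each case, which a count of 0 fixes in advance, so these splits decide nothing. The highest other splits called 1065 genes in abdominal aorta, 197 in thoracic aorta and 1 for the interaction. Mice 163 and 164 fell on the same side in each of these splits, and any gene was called in 4, 6 and 1 of 100. The 1065 and 197 genes of the highest splits point to a structure of the samples in those few splits, and what it is was not tested.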

How the results depend on the processing

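The fits without mice 165 and 173, those without the abdominal libraries of mice 163, 164 and 173, and the paired test of RNA integrity were tests chosen after the data were seen.

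Counts by genotype and for the interaction stayed at 0 in limma under each other setting, the mouse as a block and each left-out library included. Without mice 165 and 173 they were 6 and 7 for genotype in abdominal and thoracic aorta, and 0 for the interaction. The region counts stayed within 1.5 times in mice labelled XX and XO except with a mean of at least 10 required, where 3808 and 4091 were called because fewer genes (8591) were tested. With each library left out in turn they ranged from 5039 to 6792 and from 5623 to 6938. The mouse as a block gave 6806 and 6859 (duplicateCorrelation) or 5077 and 5612 (fixed), and changed no call of a named gene and no call of a list beyond those given above. Each region gene named kept its direction and its call under every setting in which it was tested. Genes of low value were not tested where a mean of at least 10 was required.

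The median of X-linked genes reversed in abdominal aorta without mice 165 and 173, from 0.0193 to -0.0124, and the cause was not tested. With each library left out it ranged from -0.0120 to 0.0401, and in thoracic aorta from -0.00869 to 0.0259. The genotype difference in RNA integrity in thoracic aorta ranged from -0.015 to 0.06. That between regions in mice labelled XO (-0.26), which did not pass after adjustment, had an unadjusted exact p of 0.0238 unpaired and 0.125 with the libraries of a mouse as pairs, by sign flips, a test that 5 pairs leave no way to pass.

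Lists called depended on the correlation. With an estimated one 0 were called in each of the 5 comparisons, against 9, 11, 13, 14 and 1 with the preset. Fry called 0 for genotype in each region and for the interaction, and 16 and 17 for region. For the interaction 6 lists were called at the preset without mice 165 and 173, 0 of them with an estimated correlation or by fry, and 5 without the abdominal libraries of mice 163, 164 and 173, and the cause was not tested. Under quantile normalization the region medians of uncalled lists changed sign for lymphatic genes in mice labelled XO, skeletal muscle and lymphocyte genes in those labelled XX (0.55 to -0.00363 for the latter), matrix proteases in those labelled XO and cell cycle in both. In mice labelled XX those of lymphatic and blood cell genes without mice 165 and 173, and of skeletal muscle, matrix protease and fibroblast genes without the 3 abdominal libraries, also changed sign. Counts of list members past the test moved by over 1.5 times for oxidative phosphorylation, as given above, and for several smaller lists. In mice labelled XO, brown adipocyte genes lower went from 11 to 7 without mice 165 and 173 and macrophage genes higher from 8 to 5 under quantile normalization, and in those labelled XX, cardiac genes lower from 3 to 7 under quantile normalization and endothelial genes higher from 5 to 2 without the 3 abdominal libraries. Count models with size factors were not run, as counts could not be recovered from the values used here, and the reads that limit genes of low value are unknown.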

Other observations

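The test of the liver list was chosen after the result was seen. Liver genes varied widely between libraries, and their list was added for that reason. The mean level of 20 liver genes was 5.37 ± 3.89 (SD, n = 5) in abdominal libraries labelled XX, from 1.31 to 10.00, against 1.56 ± 1.37 in thoracic ones. Between regions, 11 of the 20 were higher in mice labelled XX (19 adjusted over the list alone) and 0 in those labelled XO, with medians of 3.96 and 0.25. Without mice 165 and 173, 0 were called in either genotype.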
